A study of Staphylococcus aureus with 8 samples.

How the data were processed

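Total RNA of Staphylococcus aureus ATCC 29213 was labelled with Cy3 and hybridised to a custom 8-array Agilent slide, per the labels. Cultures in log phase were given no drug, 25 µM celecoxib, 3 µg/ml ampicillin or both, and harvested at 40 min, with celecoxib added 20 min after ampicillin where both were given, per the labels' protocols. The 8 arrays fall into 4 groups of 2. Replicate numbers only tell the original title from the title with a duplicate suffix. All arrays were on 1 slide and scanned on 1 date, with untreated and celecoxib arrays in 1 row and the others in the other row.

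Per the file headers, each array was read by Agilent Feature Extraction 10.7.3.1. The processed signal is an intensity on a linear scale that this software had background-subtracted and detrended within the array, with surrogate values for spots near background, per the file headers. The deposited mean signal and local background intensity are unprocessed, and other columns hold flags of 0 or 1 for background, saturation and outlier spots, per the file headers. The authors also deposited a series matrix of log2 values. How it was made is not given in the sources used here. Set against the scanner values, its columns correlated between 0.987 and 0.999 with their own arrays, and 93.9% to 97.2% of probes lay within 0.05 of a constant shift. It is therefore on the log2 scale, probes were not centred, and each array was shifted so that about its 75th percentile of probes lies at 0. Column medians were -1.12 and -0.94 (untreated), -1.09 and -0.92 (celecoxib), -1.18 and -1.47 (ampicillin) and -1.27 and -0.98 (both drugs), so scale and centring were found from the values, the exact rule of the shift stays unknown, and 1-colour values have no direction.

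The log2 of the processed signal was taken relative to each array's 75th percentile over the 15208 non-control spots. Spots with outlier flags (254 to 367 an array) were left out, saturated spots were kept, and the log2 values of the spots of a probe were averaged. Saturated spots numbered 192 to 269 on the arrays without ampicillin and 327 to 466 on the arrays with it. Of the probes, 3116 had 4 spots, and the median SD between spots of a probe was 0.042 to 0.079 on the log2 scale. A probe was well above background on an array when at least 50% of its spots were, and this held for 2915 to 2978 probes an array. Of 3612 probes, 2943 (81.5%) met this on both arrays of at least 1 group and were tested, 2908 met it on all 8 arrays and 610 on none.

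Group means were fitted over all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 residual degrees of freedom. The 6 comparisons were each drug and the combination against untreated, the combination against each drug, and the interaction, all two-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. These comparisons, the filter, the alternatives not named in the closing section as chosen later, and the rule for named genes were fixed before the data were examined. After the data were seen, 2 pooled comparisons of 4 against 4 arrays (6 residual degrees of freedom) and fits with array brightness as a covariate were added, as was the rule on the share of spots. The pooled fits held no term for the other drug. The fit was tested on simulated data with 50 changed probes at each of 4 sizes among 2943.

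Probe IDs are not paired with genes in the files, and no genome was used here, so no gene is named. The 40 gene lists fixed before the data were examined and the parts of the naming rule that need gene names were not applied. The rule's fallback, the probes with the smallest p where fewer than 5 were called, was held to 2 probes in each direction per comparison. In the pooled comparisons, too, the 2 with the smallest p in each direction are named, a choice made after seeing the data. In place of gene lists, 9 peptide classes were defined from the probe sequences after the first counts of called probes had been seen, and the 5 with at least 5 tested probes were tested with limma's camera at a preset correlation of 0.01. Of the probes, 98.8% had an open reading frame in the printed strand, against 76.4% in the reverse strand. Where several frames were open, the frame with the likeliest codon use was taken. The correlation of changes between consecutive probe numbers was computed over 2674 pairs that share no 15 bases, after removal of GC content, length and level, against 1000 shuffled orders. The numbering is the array design's own, and whether it follows the chromosome is not given in the sources used here. Python 3.11.15 was used for sequences and figures.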

Results

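Transcript levels of Staphylococcus aureus ATCC 29213, a laboratory strain of a Gram-positive pathogen, were measured on a one-colour Agilent array in log-phase cultures given no drug, celecoxib at 25 µM, ampicillin at 3 µg/ml, or both drugs, and harvested after 40 min. Celecoxib is a cyclooxygenase-2 inhibitor used against inflammation, and ampicillin is a beta-lactam that blocks cell wall cross-linking. In the combination, celecoxib was added 20 min after ampicillin, so those cells had celecoxib for a shorter time than the cells given celecoxib alone. Each of the 4 groups held 2 arrays, and nothing in the labels says that the arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. Of 3612 probes, 2943 were well above background on both arrays of at least 1 group and were tested. The files pair no probe with a gene, so probes are given by their ID and sequence. A probe was called at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment.

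The arrays differed in overall signal by up to 2.82-fold, and those of 1 group by 1.47 to 2.19-fold. The 75th percentile of the processed signal was 3176 and 6956 on the untreated arrays, 3076 and 6604 on the celecoxib arrays, 5065 and 3440 on the ampicillin arrays, and 4354 and 8669 on the arrays of the combination. After scaling, untreated replicate 1 correlated at 0.994 across probes with celecoxib replicate 1 and at 0.955 with untreated replicate 2 (probes are not independent replicates). The first principal component held 57.0% of the variance and the second 27.1%. Array brightness, the log2 of the 75th percentile, accounted for 72.7% of the variance within groups. It was used as a covariate in a second set of fits, and both this covariate and the pooled comparisons of 4 against 4 arrays were chosen after seeing the data.

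**Figure D1:**
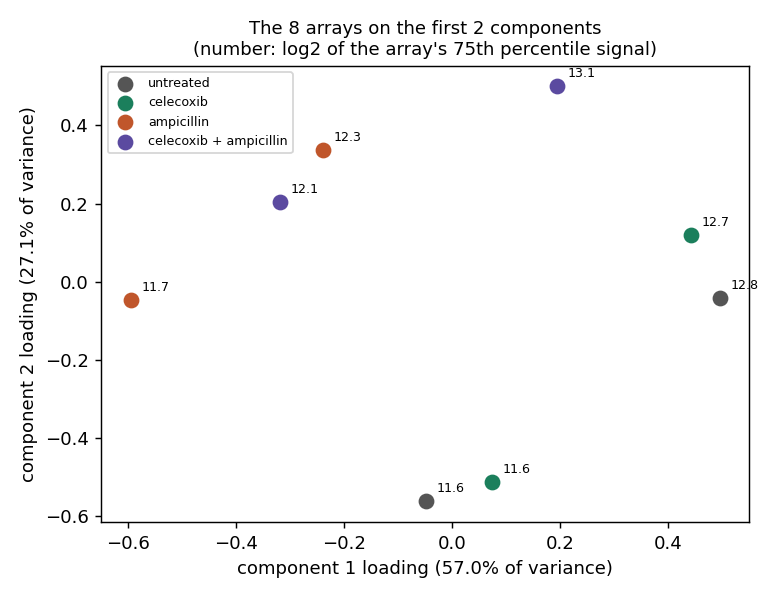
Loadings of the 8 arrays on the first 2 principal components of the 2943 tested probes, with colours for the 4 groups and the log2 of each array's 75th percentile signal beside each point. The first component holds 57.0% and the second 27.1% of the variance, and arrays of 1 group lie apart.

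The first question was what ampicillin did, with and without celecoxib. With the 4 arrays that had ampicillin pooled against the 4 that had none, 189 probes rose and 104 fell, and 148 of these 293 differed by at least 2-fold. GT_Saureus_Specific_002238 rose 4.16-fold, from a log2 level of 0.38 ± 0.30 (SD, n = 4) without ampicillin to 2.44 ± 0.27 (SD, n = 4) with it (log2 change 2.06, SE 0.19, limma adjusted p = 0.00197). GT_Saureus_Specific_003448 rose 2.96-fold, from 1.15 ± 0.11 to 2.72 ± 0.25 (SD, n = 4 each, limma adjusted p = 0.00197). Among the probes that fell, GT_Saureus_Specific_003285 went from 1.64 ± 0.54 to -0.60 ± 0.28 (SD, n = 4 each), a fall of 4.74-fold (limma adjusted p = 0.00255), and GT_Saureus_Specific_002351 from -0.75 ± 0.25 to -2.17 ± 0.17 (SD, n = 4 each), a fall of 2.67-fold (limma adjusted p = 0.00255). Levels are log2 values relative to each array's own 75th percentile.

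These 4 probes had the smallest p in each direction. The sequence of GT_Saureus_Specific_002238 is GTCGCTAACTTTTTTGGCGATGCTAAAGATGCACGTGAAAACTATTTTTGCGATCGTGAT, and that of GT_Saureus_Specific_003448 is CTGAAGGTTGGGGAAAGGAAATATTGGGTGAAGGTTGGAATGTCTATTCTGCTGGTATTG. GT_Saureus_Specific_003285 reads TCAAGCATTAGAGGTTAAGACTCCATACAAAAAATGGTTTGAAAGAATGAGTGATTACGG, and its 1 open forward frame encodes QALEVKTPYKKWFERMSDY. GT_Saureus_Specific_002351 reads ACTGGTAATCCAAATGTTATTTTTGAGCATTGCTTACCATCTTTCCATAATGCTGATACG.

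**Figure D2:**
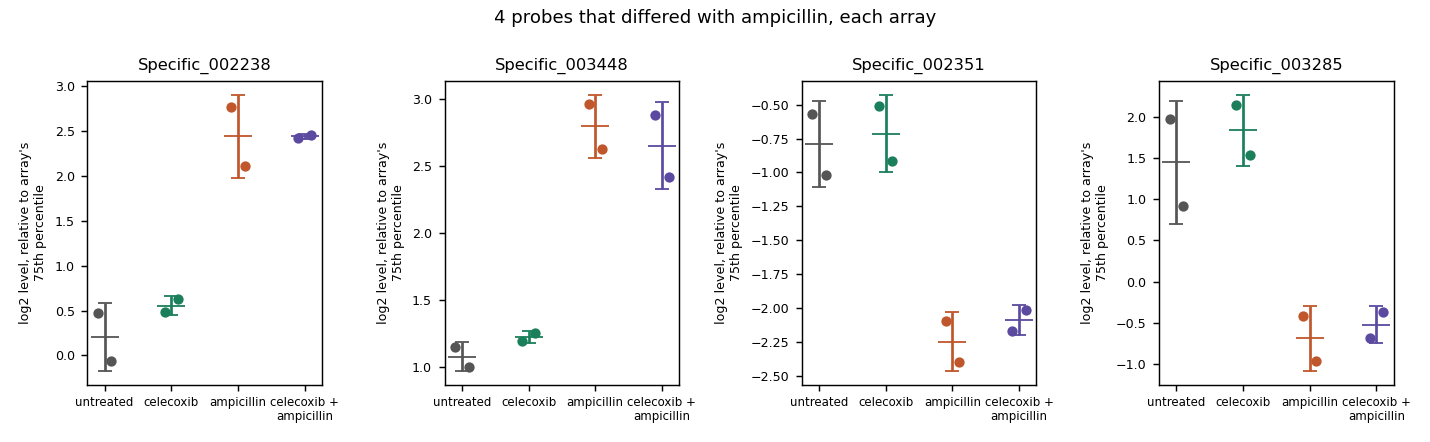
Log2 level, relative to the array's 75th percentile, of the 4 probes with the smallest p in each direction in the pooled ampicillin comparison. Points are single arrays, the horizontal marks are group means and the bars are 1 SD (n = 2), and in each panel all 4 arrays with ampicillin lie on one side of all 4 without.

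All 293 called probes had the same sign in the comparisons ampicillin against untreated and combination against celecoxib, which share no array but both enter the pooled comparison by which the probes were chosen. The probes that rose had a median log2 change of 1.11 in the first and 0.87 in the second, and those that fell had medians of -1.08 and -1.04. Over all 2943 probes the changes of these comparisons correlated at a Pearson r of 0.82, and 82.8% had the same sign (across probes, which are not independent replicates). Between single arrays the agreement was lower. The change from untreated to ampicillin correlated at 0.26 between the arrays with and without the duplicate suffix in their titles, with 59.1% of the same sign, and at 0.64 between the dimmer and the brighter arrays of the groups, with 75.8%. From celecoxib to the combination, the dimmer and the brighter arrays correlated at 0.59, with 72.4%. With brightness as a covariate, 1686 probes were called, 649 higher and 1037 lower, among them all 293. The balance of directions in that fit depended on the scaling, with 928 higher and 408 lower after scaling to the median and 584 higher and 589 lower after quantile normalization. Without the covariate, the count was 176 without untreated replicate 2, 178 and 188 without celecoxib replicates 1 and 2, 160 without ampicillin replicate 1, and 148 and 615 without replicates 1 and 2 of the combination. All arrays with ampicillin lay in 1 row of the slide and all others in the other row, so slide row and ampicillin cannot be told apart.

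**Figure D3:**
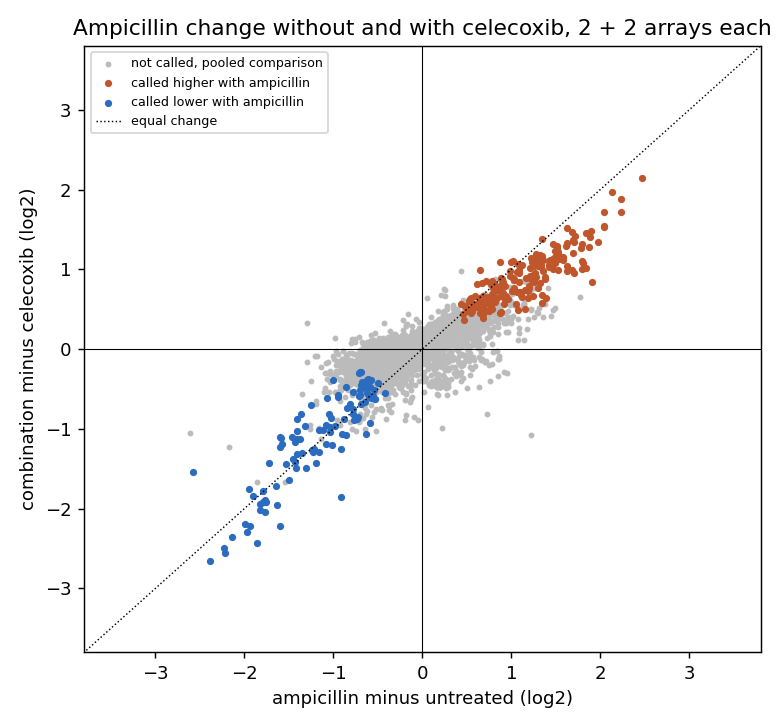
Log2 change of each of the 2943 tested probes from untreated to ampicillin (horizontal) and from celecoxib to the combination (vertical), each the difference of means of 2 arrays, with the 189 probes called higher and the 104 called lower in the pooled comparison in colour. The changes correlate at 0.82, and every coloured probe has the same sign on both axes.

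In the pairwise comparison of ampicillin against untreated cells, fixed before the data were examined, limma called no probe at 2 arrays a group. At an unadjusted p under 0.05 there were 528 probes, 285 higher and 243 lower, where 147 would fall by chance, and 242 without untreated replicate 2 and 288 without ampicillin replicate 2. The count of 147, here and below, assumes that p-values are spread evenly where nothing changed. Differences shared by many probes, as with brightness, can move counts to either side of it. Quantile normalization called 28 probes, limma with trend and robust variance 60, and a fit of these 2 groups alone 64 higher and 43 lower. The smallest p values among higher probes belonged to GT_Saureus_Specific_002238, at 0.21 ± 0.38 untreated and 2.44 ± 0.46 with ampicillin (SD, n = 2 each, limma adjusted p = 0.0798), and to GT_Saureus_Specific_001512, at -1.62 ± 0.38 and 0.85 ± 0.65 (SD, n = 2 each, limma adjusted p = 0.0798). Among lower probes they belonged to GT_Saureus_Specific_000966, with a log2 change of -1.95 (SE 0.32), and GT_Saureus_Specific_002121, with -1.37 (SE 0.23), both at a limma adjusted p of 0.0798. With brightness as a covariate, 669 probes passed, 299 higher and 370 lower, and these 4 were among them at adjusted p from 0.0201 to 0.0211. After scaling to the median the same fit called 542 higher and 121 lower, and after quantile normalization 173 higher and 115 lower. Scaling to the median raised the changes between ampicillin and untreated by 0.29 on the log2 scale at the median probe. Without either untreated array the covariate fit called 0 probes.

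The combination against untreated cells asked what both drugs did together. No probe was called by limma, with 265 at an unadjusted p under 0.05, 156 higher and 109 lower, and quantile normalization called 18. Without replicate 1 of the combination, 145 had an unadjusted p under 0.05, where 147 would by chance. GT_Saureus_Specific_002238 and GT_Saureus_Specific_001512 again had the smallest p among higher probes, with log2 changes of 2.23 (SE 0.29) and 2.46 (SE 0.35), both at a limma adjusted p of 0.208. Among lower probes, GT_Saureus_Specific_000510 stood at 1.65 ± 0.63 untreated and -0.35 ± 0.28 with both drugs, and GT_Saureus_Specific_001730 at 3.39 ± 0.64 and 1.18 ± 0.05 (SD, n = 2 each, limma adjusted p = 0.208), the latter saturated on 1 array. With brightness as a covariate 136 probes passed, 110 higher and 26 lower, including these 4, against 267 higher and 47 lower after scaling to the median and 106 and 62 after quantile normalization. The covariate fit called 0 probes without either untreated array, either celecoxib array or either array of the combination.

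The combination against celecoxib alone asked what ampicillin added to celecoxib, with the shorter celecoxib exposure in the combination as a further difference. Limma called no probe, with 232 at an unadjusted p under 0.05, 146 higher and 86 lower, and quantile normalization called 36. At that unadjusted p there were 136 without replicate 1 of the combination and 154 without celecoxib replicate 1, where 147 would fall by chance. GT_Saureus_Specific_002238 stood at 0.56 ± 0.11 with celecoxib and 2.44 ± 0.02 with both drugs (SD, n = 2 each, limma adjusted p = 0.111), and GT_Saureus_Specific_001512 had a log2 change of 2.15 (SE 0.35). GT_Saureus_Specific_001729 stood at 3.66 ± 0.73 and 1.22 ± 0.06, and GT_Saureus_Specific_002928 at 1.83 ± 0.52 and -0.07 ± 0.32 (SD, n = 2 each, limma adjusted p = 0.111). With brightness as a covariate 217 probes passed, 152 higher and 65 lower, these 4 among them, against 372 higher and 60 lower after scaling to the median and 130 and 87 after quantile normalization. With the covariate 0 passed without either untreated, either celecoxib or either combination array. Without celecoxib replicate 2 and with no covariate, 5 probes were called.

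Celecoxib was followed by 3 comparisons, and limma called no probe in any of them, with or without brightness as a covariate. Celecoxib against untreated cells had 2 probes at an unadjusted p under 0.05, 56 with the covariate and, with 1 array left out, 1 (without either ampicillin array) to 59 (without untreated replicate 2), where 147 would fall by chance. The probes with the smallest p were GT_Saureus_Specific_003501, at -2.66 ± 0.45 untreated and -1.78 ± 0.22 with celecoxib, and GT_Saureus_Specific_001930, at 0.90 ± 0.26 and 1.46 ± 0.00, both higher with celecoxib, and GT_Saureus_Specific_000590, at 0.29 ± 0.21 and -0.25 ± 0.16, and GT_Saureus_Specific_001720, at -2.33 ± 0.21 and -2.82 ± 0.14, both lower (SD, n = 2 each). All had a limma adjusted p of 1.0. The median SE without the covariate was 0.29, larger than the SD of the changes over all probes, 0.20. With errors this large against the changes, a count under 147 is no evidence that celecoxib changed nothing. The median 95% interval of a change reached 0.68 to either side on the log2 scale, and 0.40 with the covariate. In simulated data with the spread of these arrays, this comparison recovered 12% of log2 changes of 1 and 64% of changes of 2. With the covariate it recovered 70% and 90%, with 7 false calls against 0 without it. The simulated arrays were built from the fitted brightness slopes and independent noise. The covariate fit thus matched them by design, and its shares are best cases.

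The combination against ampicillin alone asked what celecoxib added to ampicillin. There were 9 probes at an unadjusted p under 0.05, and 31 with the covariate. Leaving out 1 array gave 2 (without replicate 2 of the combination) to 104 (without ampicillin replicate 1), where 147 would fall by chance. GT_Saureus_Specific_000973 stood at 1.18 ± 0.16 with ampicillin and 0.00 ± 0.77 with both drugs, and GT_Saureus_Specific_000233 at -0.17 ± 0.23 and 0.50 ± 0.31 (SD, n = 2 each, limma adjusted p = 0.797). GT_Saureus_Specific_000974, numbered next to the first of these, stood at -2.22 ± 0.26 and -3.17 ± 0.68 (SD, n = 2 each), a log2 change of -0.94 (SE 0.35). GT_Saureus_Specific_002107 stood at -7.04 ± 0.42 and -6.21 ± 0.06 (SD, n = 2 each), a log2 change of 0.84 (SE 0.29), and both had the same adjusted p. With normexp background correction the change of GT_Saureus_Specific_002107 was 0.052 (SE 0.23). The change of GT_Saureus_Specific_000233 was 0.45 (SE 0.31) after scaling to the median, and that of GT_Saureus_Specific_000973 was -0.76 (SE 0.28) with the covariate and quantile normalization. Pooling the 4 arrays with celecoxib against the 4 without gave 2 probes at an unadjusted p under 0.05, 8 with the covariate and 98 without untreated replicate 2. The one of the 2 that was well above background on all 8 arrays, GT_Saureus_Specific_003469, had a log2 change of 0.43 (SE 0.19, limma adjusted p = 0.958), and 0.26 (SE 0.17) after quantile normalization. This pooled fit held no term for ampicillin, so the ampicillin difference stayed in its error (median SE 0.24, against 0.19 for ampicillin pooled). The pool also mixed full celecoxib exposure with the shorter exposure of the combination. In simulated data this pooled comparison recovered 72% of changes of 1 on the log2 scale and 16% of changes of 0.5. The simulated data held no ampicillin difference, so these shares may be too high for the real arrays. The changes from untreated to celecoxib and from ampicillin to the combination correlated at an r of 0.26, and 59.6% had the same sign (across probes). Between the dimmer and the brighter arrays of the groups, the change from untreated to celecoxib correlated at 0.058, with 49.8% of the same sign, and that from ampicillin to the combination at 0.48, with 73.9%. The changes from ampicillin to the combination correlated at 0.88 across probes with the slope of each probe on array brightness, and the arrays of the combination were brighter by 0.56 on the log2 scale.

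The interaction asked whether the change from ampicillin to the combination differed from the change from untreated to celecoxib. Limma called no probe, with 4 at an unadjusted p under 0.05, 40 with the covariate and, with 1 array left out, 0 (without replicate 2 of the combination) to 60 (without untreated replicate 1). The smallest p belonged to GT_Saureus_Specific_003501, with a log2 difference of -1.20 (SE 0.44), and GT_Saureus_Specific_000063, with -2.30 (SE 0.86), which was saturated on 1 array. Among higher probes it belonged to GT_Saureus_Specific_002107, with 0.86 (SE 0.40), and GT_Saureus_Specific_000581, with 1.10 (SE 0.53). With normexp background correction these 2 were 0.020 (SE 0.32) and 0.34 (SE 0.27), and the latter was 0.71 (SE 0.19) with the covariate. Without these settings all 4 had a limma adjusted p of 0.997. Simulated interactions of up to 2 on the log2 scale were recovered in 0% of cases without the covariate, and in 66% at a size of 2 with it. The latter share is again a best case, as the simulated arrays were built from the fitted brightness slopes.

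Probes with consecutive numbers changed together between the arrays with and without ampicillin, which slide row also parts. There were 27 runs of at least 4 consecutive probe numbers with an unadjusted p under 0.05 and the same direction in the pooled comparison, 13 higher and 14 lower, and they held 143 probes. Shuffling the order of the probes 1000 times gave a mean of 1.95 runs and at most 9 (permutation p = 0.001, the smallest these permutations can give). Celecoxib pooled gave 0 such runs. Correlation between consecutive numbers was not particular to ampicillin, however. After removal of GC content, length and level it was 0.33 for ampicillin pooled, 0.23 for celecoxib pooled and 0.17 for brightness slopes. In 5 of the ampicillin runs every probe was called. The longest higher run was probes 332 to 338, with a mean log2 change of 0.62 and 4 of 7 probes called. Higher runs of 5 probes were 1523 to 1527, with a mean of 0.95 and 4 called, and 517 to 521, with 0.76 and 2 called. Of the lower runs, the longest was 3052 to 3063, with a mean log2 change of -0.48 and 2 of 12 called. The next was 3104 to 3113, where all 10 probes were lower and 9 were called, and the mean log2 level was 0.68 ± 0.22 untreated, 1.11 ± 0.60 with celecoxib, -0.91 ± 0.18 with ampicillin and -0.68 ± 0.21 with both drugs (SD, n = 2 each). GT_Saureus_Specific_003285 was the first of 8 consecutive probes that all fell, with a mean log2 change of -1.67, and GT_Saureus_Specific_001729 was the first of 7 that all fell, with a mean of -1.81.

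**Figure D4:**
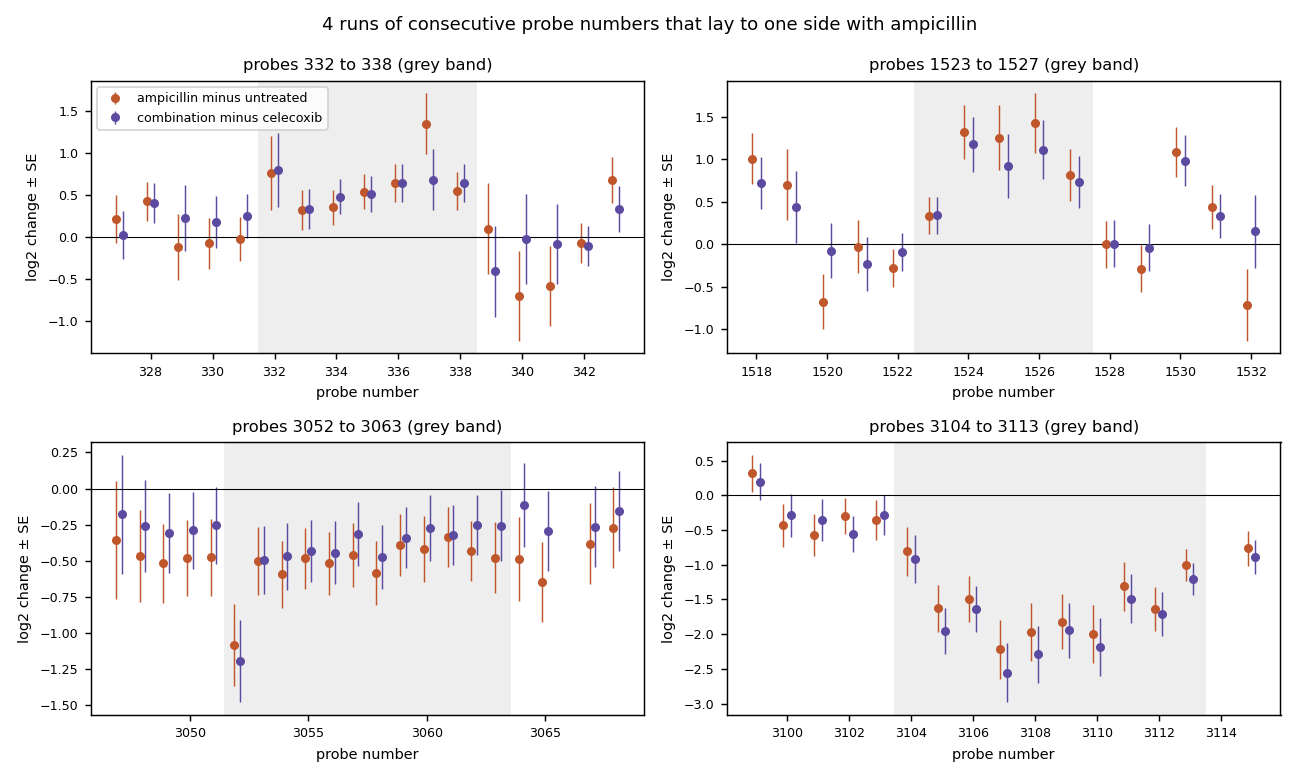
Log2 change with SE along the probe number for the longest higher run, 1 of the 2 higher runs of 5 probes and the 2 longest lower runs (grey bands) and 5 numbers to each side, from untreated to ampicillin and from celecoxib to the combination (2 arrays a group). In the run 3104 to 3113 the pooled change averages -1.69, and in the run 1523 to 1527 it averages 0.95.

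Peptide classes were read from the probe sequences and chosen after the counts of called probes had been seen. The 5 classes with at least 5 tested probes were membrane-spanning peptides (103 probes), basic peptides (76), acidic peptides (79), peptides with a Walker A nucleotide-binding loop (16) and peptides with a pair of cysteines spaced as in CXXC motifs (31). None was called by camera in any of the 8 comparisons, with a smallest adjusted p of 0.118, or a smallest adjusted p of 0.243 with an estimated correlation. Of the 40 tests, 1 had an unadjusted p under 0.05, that of the basic peptides with celecoxib pooled. In the pooled ampicillin comparison, 15 membrane-spanning, 9 basic, 15 acidic and 3 CXXC probes were called singly, and 0 of the 16 Walker A probes, against 293 of all 2943. Adjusted over the class alone, these counts were 17, 17, 17, 4 and 0. The fit with the brightness covariate, adjusted over all probes, called 59 membrane-spanning, 47 basic, 50 acidic, 17 CXXC and 12 Walker A probes (3 of these 12 higher and 9 lower), against 1686 of all 2943. The median log2 change of the acidic class was 0.03, against -0.14 for all probes (camera adjusted p = 0.417). Before the filter, the membrane-spanning rule matched 119 probes in the chosen frame and 109 in the reverse strand. The CXXC rule matched 35 and 125, so neither class is well told from chance matches. The basic rule matched 104 and 40, the acidic rule 120 and 3, and the Walker A rule 16 and 0.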

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

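All tests in this part except those of the interaction were chosen after the results were seen. In the pooled comparisons, 16 sets of 4 arrays over 8 probes were searched for an array standing apart from the others by Dixon's test, and 0 passed. For the interaction 0 probes passed the threshold in limma, with 4 at an unadjusted p under 0.05.

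For the difference between the 4 arrays with ampicillin and the 4 without, of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, called as many as 293 probes, and the highest other split called 240. That split sets the 4 arrays that are the dimmer of their group against the brighter ones and points to a structure of the arrays. With brightness as a covariate it called 0, the real split called 1686 (1 of 35 as large) and the highest other 0. The split by brightness is nearly the covariate itself, so its 0 was close to fixed. Other splits leave much of the difference between the arrays with and without ampicillin in their error. In both fits 1 of 35 is the smallest share possible, for a comparison and covariate chosen after seeing the data. Groups of 1 culture each would make fewer splits still, so chance is not excluded. A linear effect of brightness does not account for the difference, since all 293 probes kept call and sign with the covariate. The arrays with and without ampicillin differed in brightness by only 0.14 on the log2 scale, so the covariate could move the changes little. An effect of brightness that is not linear was not tested, and the changes correlated with the brightness slopes at -0.32 across probes. Noise of single probes does not account for the difference either. Changes of consecutive probe numbers correlated at 0.332 after removal of GC content, length and level, against at most 0.063 in 1000 shuffled orders. An effect of ampicillin and an effect of slide row, or of a culture, RNA or labelling batch that followed it, cannot be told apart, because 0 of the 2 rows hold arrays of both kinds.

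The next pattern was that the arrays of each group differed along 1 shared axis. Brightness removed 72.7% of the variance within groups, against at most 47.8% in the 7 other exchanges of its values within groups. The real order was the highest of 8, where 1 of 8 is the least possible, so chance is not excluded. A difference in the amount or state of labelled RNA may underlie the shared axis, which was not tested. Saturated spots do not account for it, since the share was 70.3% over the 2812 probes saturated on no array. Whether a response of single probes to the amount of target accounts for the shared axis was not settled. Brightness slopes of consecutive probe numbers correlated at 0.166 after removal of GC content, length and level, against at most 0.058 in shuffled orders. These properties explained 40.0% of the variance of the slopes. Mean level itself correlated at 0.22 between consecutive numbers, so a dependence on level not fully removed could leave such a correlation. A difference between cultures stays open, as the labels do not say whether the arrays of a group share one, and no biological explanation was tested.

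The third pattern was that the changes from ampicillin to the combination followed brightness. The arrays of the combination were brighter by 0.56 on the log2 scale, and the changes regressed on the brightness slopes, estimated within groups, with a coefficient of 0.633 and an r of 0.88 across probes. The SD of the changes went from 0.35 to 0.17 with the covariate. For the comparisons of the combination with untreated and with celecoxib, whose brightness differed by 0.39 and 0.45, the coefficients were 0.03 and -0.07, and for ampicillin against untreated, at a difference of -0.17, the coefficient was -0.60. The coefficients of these other comparisons did not follow their brightness differences. Array brightness is thus a candidate explanation for the changes from ampicillin to the combination, but not one that the other comparisons bear out. An effect of celecoxib on the cells stays open, as untested.

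For celecoxib pooled the real split called 0 probes, so that all 35 splits had to call as many and the comparison decides nothing, and the highest other, with 293, was the split by ampicillin.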

How the results depend on the processing

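The settings with brightness, the leave-one-out fits with brightness, the crossed pairing, the removal of saturated probes and both pooled comparisons were chosen after seeing the data. The counts of 0 for celecoxib against untreated, the combination against ampicillin, the interaction and celecoxib pooled stayed at 0 under every alternative run, each array left out in turn included. For the other comparisons the cause of the moves below was not tested. Quantile normalization called 28 probes for ampicillin against untreated, 18 for the combination against untreated and 36 for the combination against celecoxib. With trend and robust variance ampicillin against untreated gave 60, and with only the groups of the comparison in the fit 64 higher and 43 lower (1.1e+02 in all). With brightness as a covariate the counts were 669, 136 and 217 in the same order. They were 663, 314 and 432 with scaling to the median as well, and 288, 168 and 217 with quantile normalization as well. Ampicillin pooled gave 293, and 148 with at least a 2-fold change required, 1686 with the covariate, 1336 with the covariate and scaling to the median, and 1173 with the covariate and quantile normalization, of which 293, 287 and 280 were among the 293.

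Leaving out each array in turn, where the lone array is assumed to vary like the other groups, gave 0 to 0 probes in all fixed comparisons except 0 to 5 for the combination against celecoxib (5 without celecoxib replicate 2), and 148 to 615 for ampicillin pooled. Of the latter, the count was 176 without untreated replicate 2, 178 and 188 without celecoxib replicates 1 and 2, 160 without ampicillin replicate 1, and 148 and 615 without replicates 1 and 2 of the combination. With the covariate these ranges were 0 to 802 for ampicillin against untreated, 0 to 186 for the combination against untreated, 0 to 295 for the combination against celecoxib and 1281 to 1575 for ampicillin pooled.

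Whether the duplicate suffix of the titles pairs the arrays is open: deviations of arrays with the same suffix correlated between 0.61 and 0.79 among untreated, celecoxib and combination arrays, and between -0.68 and -0.48 with ampicillin. The ampicillin arrays stand in the opposite order to the others, in brightness too, and whether their numbers are crossed or the suffix pairs nothing was not settled. With the suffix as a replicate block 0 probes were called in each of the 6 fixed comparisons, 315 in ampicillin pooled and 0 in celecoxib pooled. A replicate block with the ampicillin arrays crossed, which also parts the dimmer from the brighter array of each group, called 1109 for ampicillin against untreated, 96 for the combination against untreated, 96 for the combination against celecoxib, 867 for ampicillin pooled, and 0 for the combination against ampicillin, the interaction, celecoxib against untreated and celecoxib pooled, where 816, 296, 50 and 47 probes had an unadjusted p under 0.05 in limma and 147 would by chance.

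Of 719 alternatives for named probes, 655 kept direction and side of the threshold, 63 kept direction and newly passed it, and 1 turned, GT_Saureus_Specific_002813 in celecoxib pooled, at -0.033 with normexp and well above background on 4 of 8 arrays. The runs of consecutive numbers numbered 15 to 92 over the settings, and the 4 runs plotted (332 to 338, 1523 to 1527, 3052 to 3063 and 3104 to 3113) kept their direction in all. No peptide class was called in any of the 64 pairs of a comparison and a setting, the main setting included. The brightest probe of a gene and the gene list tests were not run, because no probe has a gene name. Of 2943 probes that passed the filter, 2908 were well above background on all arrays, yet normexp shrank some changes.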

Other observations

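All tests in this part were chosen after the results were seen. With ampicillin, the change of a probe went with its mean level, and the pair correlated at a Spearman rho of 0.43 across probes in the pooled comparison, and 0.46 with brightness as a covariate. The probes called higher had a median log2 level of 0.72 and those called lower -0.55, against -0.65 for all tested probes, and with the covariate these medians were 0.63 and -1.20. Saturated spots were more numerous on every array with ampicillin (327 to 466) than on every array without (192 to 269). Whether this bears on the link with level was not tested. Without the probes saturated on any array, the pooled fit called 293 probes, 276 of them among the 293 of the main fit. The changes from celecoxib to the combination had an SD of 0.44 over all probes, against 0.61 from untreated to ampicillin. Whether these SDs differ was not tested.

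Pairs of probes that share at least 25 bases, 137 pairs over 173 probes, had nearly equal changes, with an r of 0.98 for ampicillin pooled and 0.96 for celecoxib pooled and median differences of 0.04 and 0.03 on the log2 scale. For celecoxib pooled, changes of consecutive probe numbers correlated at 0.23 after removal of GC content, length and level, and at 0.29 with brightness as a covariate, against at most 0.06 in shuffled orders, although no probe was called. Brightness slopes showed such a correlation too, so it does not tell a drug effect from a difference between cultures. Spots of consecutive numbers lay within 2 steps of each other on the slide in 0.972% of pairs, against 1.35% of random pairs.

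Between celecoxib and untreated arrays, 12 probes were well above background on both untreated arrays and neither celecoxib array and 0 the other way round. For ampicillin against untreated the counts were 5 and 0, and for the combination 4 and 1 against untreated, 0 and 2 against ampicillin and 0 and 0 against celecoxib. No probe was well above background on all 4 arrays with ampicillin and none of those without, or the reverse. All these counts rest on a threshold near background. Between celecoxib and untreated, 5 of the 2943 tested probes were lower by at least 2-fold, and none was called. In all, 2940 and 2978 probes were well above background on the untreated arrays, and 2915 and 2951 on the celecoxib arrays.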
